A study of Mus musculus with 6 samples.

How the data were processed

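Libraries came from the initial segment and caput of the epididymis of 12-week-old wild-type mice after intraperitoneal injection of DMSO (3 libraries) or busulfan (3 libraries). RNA was extracted with RNeasy and libraries were made with a stranded poly(A) kit (TruSeq stranded mRNA), per the labels' protocols, and sequenced on an Illumina instrument. The dose and the time between injection and collection are not given in the sources used here. The labels number the replicates 1 to 3 in each group and do not say that each number is a separate mouse. The p-values therefore measure the spread between these samples, which may be technical in part.

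The authors deposited 1 table of normalized FPKM, a unit named per the file headers, with 24346 gene rows and 6 columns that each carry the title of 1 sample. TopHat2 2.1.1, Cufflinks 2.2.1 and the genome build mm10 are named in the submitters' processing notes, with no role or order. How the FPKM were normalized between libraries and which annotation and strand setting were used are not given in the sources used here. FPKM divide by transcript length and by library size, so a fall of very abundant genes can raise the values of the others unless the scaling corrects for it. Of the rows, 5596 were at 0 in every library. Of 272 rows of ribosomal, proteasome, elongation factor, respiratory chain, RNA polymerase II and spliceosome genes, 1 was at 0 in every library. Whether that 0 is a failed estimate or a gene without expression in this tissue was not determined. An exact 0 could be either, so rows with a 0 in a library are given library by library. Coordinates came from GENCODE M21 (GRCm38, the assembly also called mm10), matched by gene symbol, which placed 23268 rows (95.6%) on 1 gene model.

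No library sizes are in the table, so depth was read from low values. In 3054 genes under 0.5 FPKM in every library, 64.6% of values were whole multiples of the gene's smallest step within 0.05 (chance gives 10%), and the ratio of steps between libraries gave relative depths of 1, 1.08 and 1.082 for the DMSO replicates and 0.965, 1.056 and 0.923 for the busulfan replicates. With the length of 57 genes that have a single transcript of over 3000 bases, DMSO replicate 1 came to about 12200000 fragments (quartiles 9800000 to 12400000), which puts the others at 11300000 to 13200000. The ratio was fitted on the same low genes. Those lying at it were 250 of 1691 compared (busulfan replicate 3) to 326 of 1868 (DMSO replicate 2). The chance value of 10% takes no account of that fit. A step also carries the authors' unknown normalization between libraries, so a ratio of steps need not be a ratio of depths. The depths are therefore a rough estimate, and counts were not recovered for most genes, so no count test was run. At this depth, genes of a few FPKM rest on few fragments.

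Genes with a mean of at least 1 FPKM over the 6 libraries (12848) were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with a mean-variance trend and all 6 libraries in the fit, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Log2 changes are busulfan minus DMSO on the log2(FPKM + 1) scale, which understates the change of low genes, and the largest changes are ranked on that scale, which can differ from the order of folds. Folds are ratios of the mean FPKM of the groups. Of 32 gene lists fixed before the data were examined, the 26 with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. Members were also counted with adjustment over the list alone. Some genes are in more than 1 list. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

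The genes named were chosen by a rule fixed before the data were examined. It took the 10 largest rises and 10 largest falls among genes past the threshold with a group mean of at least 5 FPKM in a group and with groups that did not overlap. It also took the 5 most abundant genes past the threshold and up to 4 members per list with the largest changes past the threshold (or the 2 most abundant members if none passed). Not every gene the rule takes is reported here. Genes outside the rule are said to be named after their values were seen.

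The tests were tested on simulated data with the means and spread of these libraries. Of genes changed by 0.5, 1 and 2 on the log2 scale, 57.6% (38 of 66), 95.5% (64 of 67) and 100% (67 of 67) were recovered, with 3 false calls among 12648 unchanged genes. A simulated shift of the proliferation list by -0.5 was found by camera with 0 other lists called. The simulated genes varied independently of each other and most were unchanged. In the real libraries the estimated correlation of that list was 0.28 and 42.8% of tested genes changed. The simulation therefore does not show how often camera miscalls lists whose members vary together.

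No pair of libraries had identical values. Alternatives fixed before the data were examined were a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, quantile normalization, median scaling, no trend, array weights, a minimum log2 change of 1, a replicate block, the other list tests and leaving out each library in turn.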

Results

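Messenger RNA levels were measured by poly(A) RNA sequencing in the proximal epididymis of 12-week-old wild-type mice. The tissue was the initial segment together with the caput, the part of the duct that receives sperm and fluid from the testis first. Mice were injected intraperitoneally with busulfan, a DNA-alkylating drug that depletes the germ cells of the testis, or with the solvent dimethyl sulfoxide (DMSO). Each group had 3 libraries. Values were the authors' normalized FPKM (fragments scaled by transcript length and library size) for 24346 genes. The summed FPKM of a library lay between 707219 and 732495 in the DMSO group and between 625087 and 666662 in the busulfan group. The 10 most abundant genes took 16.9% to 17.8% of that sum, and 12612 to 12774 genes per library reached 1 FPKM. From the spacing of low values the sequencing depth was estimated roughly at 11300000 to 13200000 fragments per library. Relative to DMSO replicate 1 it ran from 0.923 to 1.082. That spacing also carries the authors' normalization, so these depths are uncertain. On the first principal component, which held 79.1% of the variance, the DMSO libraries lay between -36.4 and -30.2 and the busulfan libraries between 33.8 and 34.3. Spearman correlations across genes were 0.9859 to 0.9899 within groups and 0.9365 to 0.949 between them.

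The comparison of busulfan with DMSO asked how the transcriptome of the proximal epididymis differs in mice given a drug that removes germ cells. It cannot separate an action of the drug on the epididymis from an action through the loss of germ cells. The 10 genes with the largest falls on the log2(FPKM + 1) scale kept under 1% of their DMSO level, and several of them were among the most abundant transcripts of the DMSO libraries. The β-defensin gene Defb48 (NCBI gene 432867; chromosome 14, 62977524 to 62984510 on GRCm38) fell from 7778 ± 489 to 1.81 ± 0.245 FPKM (mean ± SD, n = 3 per group), a 4290-fold fall with a log2 change of -11.44. The lipocalin genes Lcn8 (NCBI gene 78076; chromosome 2, 25653120 to 25656217) and Lcn9 (NCBI gene 77704; chromosome 2, 25823153 to 25825537), which encode secreted carriers of small lipophilic molecules, fell from 12280 ± 457 to 26.5 ± 3.67 FPKM and from 7289 ± 178 to 12.7 ± 11.5 FPKM. The β-defensin gene Defb25 fell 102-fold, from 12430 ± 390 to 122 ± 30.6 FPKM. Teddm2 fell 815-fold and the predicted gene Gm4846 fell 280-fold. The remaining genes among these 10 were Rnase10, Cst8, Adam28 and Gm17677, whose values were 300 to 323 FPKM in the DMSO libraries and 0, 0.484 and 0.555 in the busulfan libraries.

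Rises were smaller. Cdkn1a, which encodes the cell-cycle inhibitor p21 (NCBI gene 12575; chromosome 17, 29090976 to 29100727), rose 3.59-fold, from 14.7 ± 1.72 to 52.9 ± 3.81 FPKM. The nuclear long noncoding RNAs Neat1 and Malat1 rose from 54.2 ± 10.1 to 197 ± 25.6 FPKM and from 11.9 ± 1.37 to 36.4 ± 8.58 FPKM. Muc5b, which encodes a gel-forming mucin, rose from 19.7 ± 7.68 to 57.0 ± 10.3 FPKM. The potassium channel gene Kcnt1 rose 4.11-fold, Ly6f rose 4.80-fold and 4930426D05Rik rose 5.82-fold. Spag11a rose from 360 ± 206 to 1018 ± 297 FPKM. Its paralog Spag11b, named after its values were seen, stood at 18030 ± 703 and 19720 ± 1134 FPKM (limma adjusted p = 0.306), and fragments of the pair may have been divided unevenly, so the value for Spag11a is uncertain. The microRNA gene Mir8094 was listed at 0 in the DMSO libraries and at 70.0, 48.0 and 18.3 FPKM in the busulfan libraries. It lies inside Ddx39b on the same strand of chromosome 17 (Ddx39b, 35241746 to 35253707), so fragments of the host gene cannot be separated from it.

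The 5 most abundant of the changed genes, by the mean over all 6 libraries, were secreted products of the epididymal epithelium. Gpx5, which encodes a secreted glutathione peroxidase, stood at 35290 ± 656 FPKM in the DMSO libraries and 28640 ± 1786 in the busulfan libraries (limma adjusted p = 0.044). That call was lost on leaving out any library except busulfan replicate 1 (limma adjusted p of 0.0637 to 0.179). It was also lost after quantile normalization, which cannot judge this gene. That method gives the top-ranked gene the same value in every library, so its log2 change became -6.73e-16 by construction. Clusterin (Clu) rose 2.08-fold to 14650 ± 850 FPKM, Lcn5 rose 1.96-fold to 10790 ± 2768 FPKM and Defb18 rose 1.41-fold to 10240 ± 145 FPKM. Defb20 fell 1.72-fold, from 8318 ± 362 to 4830 ± 385 FPKM.

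With limma on log2(FPKM + 1) and a Benjamini-Hochberg adjusted p under 0.05, 5501 of 12848 tested genes (42.8%) differed, 2668 higher and 2833 lower with busulfan. After quantile normalization the split turned, with 3228 higher and 2302 lower. The median absolute log2 change of these genes was 0.42. Changes of at least 1 on the log2 scale were mostly falls, with 435 genes lower and 140 higher. Changes of at least 2 comprised 164 falls and 2 rises, Mir8094 and Pet117, the latter named after its values were seen (0.222 ± 0.141 to 4.36 ± 1.15 FPKM). The genes lower by at least 1 held 17.1% of the summed FPKM in the DMSO libraries and 1.7% in the busulfan libraries. The groups did not overlap for 7020 tested genes (54.6%), where chance gives 10%.

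**Figure D1:**
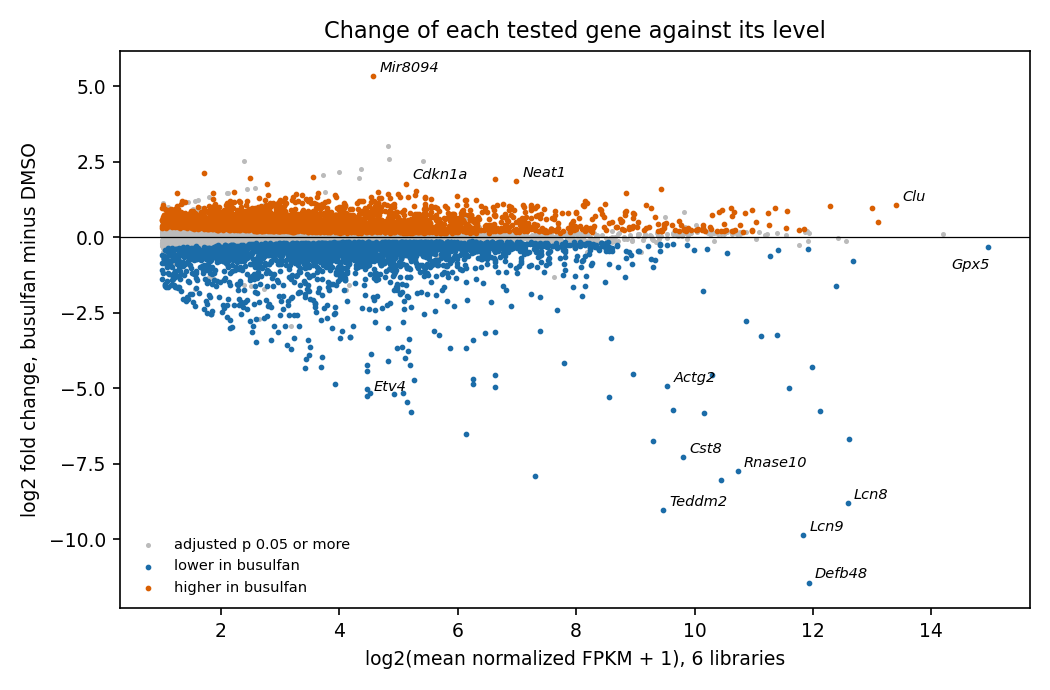
Log2 fold change of each of the 12848 tested genes (busulfan minus DMSO, on log2(FPKM + 1)) against log2 of its mean normalized FPKM plus 1 over the 6 libraries. Blue points are lower and orange points higher at an adjusted p under 0.05, and grey points did not pass; falls reach -11.44 (Defb48), while the highest rise that passed is Mir8094 at 5.35.

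The first list held genes of the initial segment tied to factors carried in the luminal fluid from the testis. Whether each member depends on such factors was not tested. Of its 17 tested genes, 12 fell, 3 rose and 2 did not pass, with a median log2 change of -3.64. The list stood lower than other genes by camera with a preset correlation (adjusted p = 3.95e-06), but not with an estimated correlation (adjusted p = 0.793). Besides Lcn8 and Lcn9, the ribonuclease-family gene Rnase10 (NCBI gene 75019; chromosome 14, 51007751 to 51010758) fell from 3377 ± 374 to 15.5 ± 6.31 FPKM, and Cst8 (NCBI gene 13012; chromosome 2, 148798785 to 148805595), a cystatin-related gene, fell from 1781 ± 44.2 to 10.9 ± 4.14 FPKM. Adam28 (NCBI gene 13522; chromosome 14, 68606027 to 68655842), which encodes a membrane metalloprotease, fell from 1253 ± 107 to 10.6 ± 1.61 FPKM. Ovch2, a serine protease-like gene, fell from 950 ± 44.0 to 40.2 ± 3.41 FPKM. Ros1 (NCBI gene 19886; chromosome 10, 52045721 to 52195244), which encodes the receptor tyrosine kinase required for differentiation of the initial segment, fell less, from 64.8 ± 4.63 to 33.7 ± 1.79 FPKM, so that 52.0% remained. The 3 members that rose were Ggt1 (75.5 ± 15.4 to 154 ± 17.3 FPKM), Rnase9 (985 ± 381 to 1752 ± 520 FPKM) and Rnase13 (370 ± 74.9 to 630 ± 89.1 FPKM), while Penk and Srd5a2 had log2 changes of 0.20 and 0.14 that did not pass. Ovch2, Rnase9, Rnase13, Penk and Srd5a2 were named after their values were seen. In the same libraries 9 of 13 endothelial markers and 12 of 16 fibroblast and matrix genes fell, with medians of -0.57 and -0.59, and the spermatid transcripts Prm1, Tnp1 and Tnp2 fell. With p-values adjusted over the list alone, 12 members were lower and 4 higher.

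**Figure D2:**
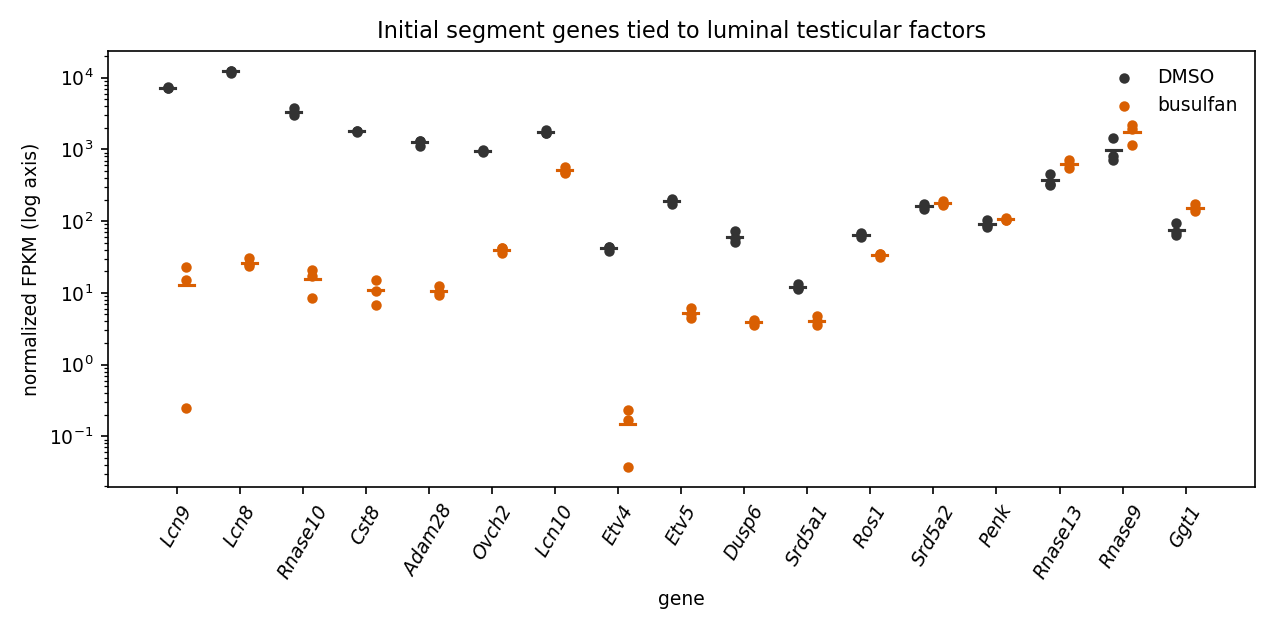
Normalized FPKM (log axis) of the 17 tested initial segment genes in each DMSO library (black) and busulfan library (orange), with bars at the group means. Lcn8, for example, drops from a mean of 12280 to 26.5, Ros1 drops from 64.8 to 33.7, and Ggt1 is higher with busulfan.

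Of 18 tested target and feedback genes of the ERK kinase pathway, which growth factor receptors such as ROS1 activate, 15 fell, none rose and 3 (Egr1, Fos and Myc, named after their values were seen) did not pass, with a median log2 change of -1.73. Camera gave an adjusted p of 6.78e-10, against an adjusted p of 0.793 with an estimated correlation. The transcription factor genes Etv4 and Etv5 (Etv5, NCBI gene 104156; chromosome 16, 22381309 to 22439719) fell from 42.3 ± 3.26 to 0.147 ± 0.10 FPKM and from 191 ± 16.7 to 5.23 ± 0.840 FPKM. The genes of the ERK phosphatases Dusp6 and Dusp4 fell 15.6-fold and 14.5-fold. The counts adjusted over the list alone were again 15 lower and 0 higher. Etv4, Etv5 and Dusp6 are also in the initial segment list, and the endothelial and fibroblast markers fell in the same libraries (medians -0.57 and -0.59). Of 14 tested ROS1 signalling parts, the kinases and adaptors of the pathway itself, 3 fell (Ros1, Map2k1 to 76.4% of its DMSO level, and Map2k2, named after its values were seen), 2 rose (Araf, 1.59-fold, and Frs2, 1.31-fold) and 9 did not pass (camera adjusted p = 0.756; fry adjusted p = 0.0151, direction down), with the same counts when adjusted over the list alone.

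Transcripts of haploid germ cells were low in both groups and some of them fell. Protamine and transition protein mRNAs, which are made in spermatids, were above 3 FPKM in each DMSO library. Prm1 stood at 13.5, 10.7 and 7.87 FPKM in the DMSO libraries and at 0, 1.10 and 2.1 in the busulfan libraries. Tnp1 stood at 6.84, 6.02 and 4.74 FPKM against 0, 0.324 and 0.371, and Tnp2 at 8.81, 5.71 and 3.66 FPKM against 0.228, 0 and 1.43. Prm2 stood at 15.9, 12.6 and 9.50 FPKM against 0, 1.95 and 6.69, and its call was lost without DMSO replicate 1 or 2 (adjusted p of 0.0543 to 0.0647) and with a pseudocount of 0.1 (adjusted p = 0.0578). Of 18 tested sperm and spermatid transcripts, 5 fell, 2 rose and 11 did not pass (median log2 change -0.17, camera adjusted p = 0.389); adjusted over the list alone, 5 were lower and 1 higher. The members that rose were Smcp, which encodes a sperm mitochondrial protein (7.5 ± 0.869 to 21.2 ± 6.84 FPKM), and Hspa1l; both were named after their values were seen. Among 6 tested Sertoli cell markers, the inhibin gene Inha rose 3.09-fold to 17.3 ± 1.29 FPKM and Clu and Rhox5 (named after its values were seen) also rose, while Sox9 and Defb36 fell 1.83-fold and 3.23-fold and 1 did not pass (camera adjusted p = 0.756; fry adjusted p = 0.00173, direction up). Of 2 tested Leydig cell markers, the steroidogenic enzyme gene Cyp17a1 stood at 2.05 ± 0.503 and 3.16 ± 0.374 FPKM (adjusted p = 0.0295; 0.0531 to 0.102 without DMSO replicate 3, busulfan replicate 1 or busulfan replicate 2), and the other did not pass. The Sertoli and Leydig counts were the same when adjusted over the list alone. Of the 12 genes in the Sertoli list, only these 6 reached the mean of 1 FPKM needed for testing. Clu, Rhox5 and Defb36 are also in the caput secreted, androgen-responsive and β-defensin lists. The counts and p-values of the Sertoli list therefore do not speak for Sertoli cells in this tissue.

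Secreted proteins of the caput that act on maturing sperm moved in both directions. Of 26 tested members, 12 fell, 12 rose and 2 did not pass; the median log2 change was 0.05 and the mean -0.60 (camera adjusted p = 0.756; fry adjusted p = 0.000142, direction down). Ly6g5b fell from 2239 ± 115 to 38.5 ± 3.23 FPKM and the sperm-coating protein gene Crisp1 from 736 ± 12.6 to 18.5 ± 5.16 FPKM. The cystatin genes Cst11 and Cst12 fell from 7727 ± 492 to 390 ± 27.1 FPKM and from 4862 ± 66.6 to 518 ± 31.3 FPKM. The β-defensins, antimicrobial peptides of which many are expressed in the epididymis, were likewise divided, with 12 of 31 tested members higher, 7 lower and 12 not past the threshold. Their median log2 change was 0.47 and their mean -0.34 (camera adjusted p = 0.389, direction up; fry adjusted p = 0.0136, direction down). Besides Defb48 and Defb25, Defb47 fell from 5955 ± 51.6 to 213 ± 121 FPKM and Defb6 fell 5.17-fold. Some β-defensin sequences are similar to each other, which makes single members uncertain. Of 14 tested androgen-responsive epididymal genes, 7 rose, among them Lcn5, 5 fell and 2 did not pass (median 0.20, mean -0.16, camera adjusted p = 0.839, direction up; fry adjusted p = 0.00543, direction down). Crisp1 fell by 5.27 on the log2 scale, and the retinaldehyde dehydrogenase gene Aldh1a1 fell from 803 ± 3.90 to 483 ± 31.6 FPKM. The β-defensins, adjusted over the list alone, had 14 higher and 7 lower, and the counts of the caput secreted and androgen-responsive lists were unchanged.

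Of 24 tested proliferation genes, 16 fell, none rose and 8 did not pass, with a median log2 change of -0.50. Camera gave an adjusted p of 9.48e-05, against an adjusted p of 0.793 with an estimated correlation and 0.438 when only genes with a mean of at least 5 FPKM were tested, which left 5 members with a median of -0.34. Endothelial and fibroblast markers fell in the same libraries (medians -0.57 and -0.59). The ribonucleotide reductase gene Rrm2 fell from 3.54 ± 0.550 to 1.17 ± 0.408 FPKM, the proliferation antigen gene Mki67 from 2.07 ± 0.244 to 0.795 ± 0.318 FPKM and the cyclin gene Ccnb2 from 3.78 ± 0.362 to 1.92 ± 0.0831 FPKM. There were 17 lower and 0 higher when adjusted over the list alone. Of 25 tested targets of p53, the transcription factor activated by DNA damage, 10 rose, 5 fell and 10 did not pass (median 0.10, camera adjusted p = 0.389; fry adjusted p = 0.0377, direction up). Besides Cdkn1a, the exonuclease gene Aen rose 1.74-fold and the receptor gene Eda2r rose from 0.537 ± 0.180 to 1.59 ± 0.402 FPKM, whereas Ddit4l fell from 198 ± 6.77 to 39.7 ± 2.76 FPKM. The p53 target Mdm2, named after its values were seen, stood at 15.9 ± 0.361 and 15.8 ± 0.186 FPKM (adjusted p = 0.907). Of 20 tested apoptosis genes, 5 rose, among them Bmf (1.94-fold) and the anti-apoptotic Bcl2l1 (1.43-fold), and 4 fell, among them Bbc3 (1.75-fold) and Xiap (1.58-fold), while 11 did not pass (camera adjusted p = 0.869). The p53 targets adjusted over the list alone had 10 higher and 6 lower, and the apoptosis counts did not differ.

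Of 20 tested genes of cholesterol synthesis and uptake, 15 fell, 2 rose and 3 did not pass, with a median log2 change of -0.36. Camera gave an adjusted p of 9.48e-05, against an adjusted p of 0.793 with an estimated correlation. Endothelial and fibroblast markers fell in the same libraries (medians -0.57 and -0.59). Dhcr7, which encodes the enzyme of the last step of cholesterol synthesis in the Kandutsch-Russell branch, fell from 9.23 ± 1.23 to 1.31 ± 0.126 FPKM. Idi1, Lss and Cyp51, which encode earlier enzymes of the pathway, fell 2.08-fold, 2.09-fold and 1.65-fold. The counts adjusted over the list alone were the same. The glutathione, endoplasmic reticulum stress and retinoid lists had no shift past the threshold by camera or fry. Of 26 tested glutathione and oxidative stress genes, 9 rose and 9 fell (camera adjusted p = 0.869): the γ-glutamyltransferase-family gene Ggt7 fell from 31.9 ± 5.14 to 2.28 ± 0.281 FPKM, and Ggt1, Gsta3 and the sulfiredoxin gene Srxn1 rose 2.05-fold, 2.03-fold and 1.93-fold. Of 21 tested endoplasmic reticulum stress genes, 4 rose (Chac1, Ddit3, Asns and Pdia4, by 1.25-fold to 2.0-fold) and 5 fell (camera adjusted p = 0.756). Of 14 tested retinoid pathway genes, 4 rose, among them Rarres1 and the receptor gene Rara, and 2 fell, Aldh1a1 and the retinoic acid-degrading Cyp26b1 (camera adjusted p = 0.839). Adjusted over the list alone, the glutathione list had 10 lower and 9 higher, and the stress and retinoid counts were unchanged.

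Transport and junction genes of the epithelium also moved in both directions. Of 13 tested principal cell solute transport genes, 6 fell and 3 rose (camera adjusted p = 0.722; fry adjusted p = 0.0151, direction down). The chloride channel gene Cftr fell from 14.1 ± 1.40 to 4.08 ± 0.552 FPKM, the water and glycerol channel gene Aqp9 from 50.5 ± 2.17 to 20.2 ± 6.27 FPKM and the bicarbonate cotransporter gene Slc4a4 from 20.0 ± 1.70 to 9.09 ± 1.36 FPKM, whereas the amino acid transporter gene Slc38a5 rose from 2123 ± 63.2 to 3899 ± 298 FPKM. Of 18 tested epithelial polarity, junction and keratin genes, 8 fell and 6 rose (camera adjusted p = 0.839). The claudin gene Cldn10 fell from 139 ± 16.3 to 12.5 ± 2.71 FPKM and the ezrin gene Ezr from 346 ± 13 to 202 ± 3.23 FPKM, while Krt19 and Espn rose 1.76-fold and 1.99-fold. Markers of clear cells, the proton-secreting cells of the epididymal epithelium, were 6 higher and 2 lower of 11 tested (median 0.42, camera adjusted p = 0.144; fry adjusted p = 0.0136, direction up). Among them the transcription factor gene Foxi1 rose from 33.0 ± 3.59 to 65.9 ± 2.36 FPKM and the carbonic anhydrase gene Car12 rose 2.14-fold. At low levels, the proton pump subunit gene Atp6v0a4 rose 1.76-fold (2.50 to 4.38 FPKM) and Insrr rose 2.31-fold (0.700 to 1.62 FPKM). The 2 that fell, named after their values were seen, were Atp6v0d2 (51.3 ± 0.921 to 33.4 ± 0.861 FPKM) and Car2 (15.9 ± 1.26 to 11.65 ± 0.79 FPKM). Of 9 tested basal cell markers, 4 fell (Krt17, Itga6, Cldn1 and Trp63, by 1.53-fold to 4.52-fold) and 2 rose, Krt5 and Krt14, both named after their values were seen (camera adjusted p = 0.543; fry adjusted p = 0.00608, direction down). Of 10 tested efferent duct and multiciliated cell markers, 3 fell, among them Aqp1 (1.76-fold) and Car4 (2.95-fold), and 3 rose, among them Esr1 (1.59-fold) and Ccno (1.52-fold; camera adjusted p = 0.869). Adjusted over the list alone, 4 solute transport genes and 7 clear cell markers were higher, and the other counts of these lists were unchanged.

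Of 13 tested endothelial markers, 9 fell, none rose and 4 did not pass, with a median log2 change of -0.57 (camera adjusted p = 0.000406; adjusted p = 0.793 with an estimated correlation). Plvap, which encodes a protein of endothelial fenestrae, fell from 41.4 ± 4.81 to 5.09 ± 0.692 FPKM. The VEGF receptor genes Kdr and Flt1 fell 3.18-fold and 2.77-fold, and Emcn fell 2.63-fold. Of 16 tested fibroblast and matrix genes, 12 fell, none rose and 4 did not pass, with a median of -0.59 (camera adjusted p = 0.000407; adjusted p = 0.862 with an estimated correlation). Among them the fibroblast receptor gene Pdgfra fell from 61.2 ± 5.79 to 16.5 ± 1.59 FPKM, and the collagen genes Col1a1 and Col3a1 fell 1.90-fold and 1.79-fold. Of 13 tested smooth muscle markers, 2 fell, 1 rose (Synm, 1.22-fold) and 10 did not pass (median 0.07, mean -0.31, camera adjusted p = 0.869). The γ-smooth-muscle actin gene Actg2 fell from 1443 ± 110 to 46.8 ± 6.0 FPKM, while Acta2, named after its values were seen, stood at 250 ± 15.1 and 262 ± 16.8 FPKM (adjusted p = 0.466). Adjusted over the list alone, the counts of these 3 lists were the same.

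Of 18 tested macrophage and dendritic cell markers, 7 fell, 1 rose and 10 did not pass (median -0.25, camera adjusted p = 0.109; 0.00284 without busulfan replicate 1). Those with the largest falls on the log2(FPKM + 1) scale were the class II antigen presentation genes H2-Ab1 (1.77-fold), H2-Aa (1.62-fold), H2-Eb1 (1.67-fold) and Cd74 (1.65-fold). The H2-Eb1 call was lost without DMSO replicate 1, DMSO replicate 3, busulfan replicate 2 or busulfan replicate 3 (log2 changes of -0.79 to -0.54). Of 19 tested interferon-stimulated genes, 2 rose (Irf9, 1.84-fold, and Irf7, 1.26-fold), 2 fell (Ddx58, 1.26-fold, and Rsad2, 1.60-fold) and 15 did not pass (camera adjusted p = 0.621). Among 11 tested cytokine and acute-phase genes, the siderophore-binding lipocalin gene Lcn2 fell from 8109 ± 185 to 2633 ± 69.9 FPKM, Nfkbia rose 1.45-fold and 9 did not pass (camera adjusted p = 0.756; fry adjusted p = 0.0151, direction down). Adjusted over the list alone, the counts of these 3 lists were the same. No T and NK cell marker and no neutrophil marker reached the mean of 1 FPKM needed for testing. The highest DMSO means were 0.975 FPKM for the T and NK markers and 0.632 FPKM for the neutrophil markers. S100a8 stood at 0.403, 1.12 and 0.372 FPKM in the DMSO libraries and at 0.418, 0 and 0 in the busulfan libraries, and the DMSO means of Lck, Cd3g and Csf3r were 0.901, 0.964 and 0.541 FPKM. Xbp1, the 1 tested B and plasma cell marker, stood at 107 ± 7.48 and 94.0 ± 1.36 FPKM (adjusted p = 0.0387; 0.43 after quantile normalization and 0.0594 to 0.116 without any library except DMSO replicate 2). Xbp1 is also in the endoplasmic reticulum stress list, so its value does not speak for B and plasma cells. Of 4 tested adipocyte markers, Plin4 rose 2.69-fold and Lipe fell 1.36-fold. Of 3 tested red blood cell markers, Hba-a1 stood at 59.3 ± 26.6 and 29.5 ± 7.21 FPKM with overlapping groups (adjusted p = 0.0385; 0.0604 after quantile normalization and 0.0773 to 0.115 without DMSO replicate 2 or 3 or busulfan replicate 2 or 3). Hba-a1 has a near-identical copy, Hba-a2, so its value is uncertain. The counts of these 3 small lists did not differ when adjusted over the list alone.

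**Figure D3:**
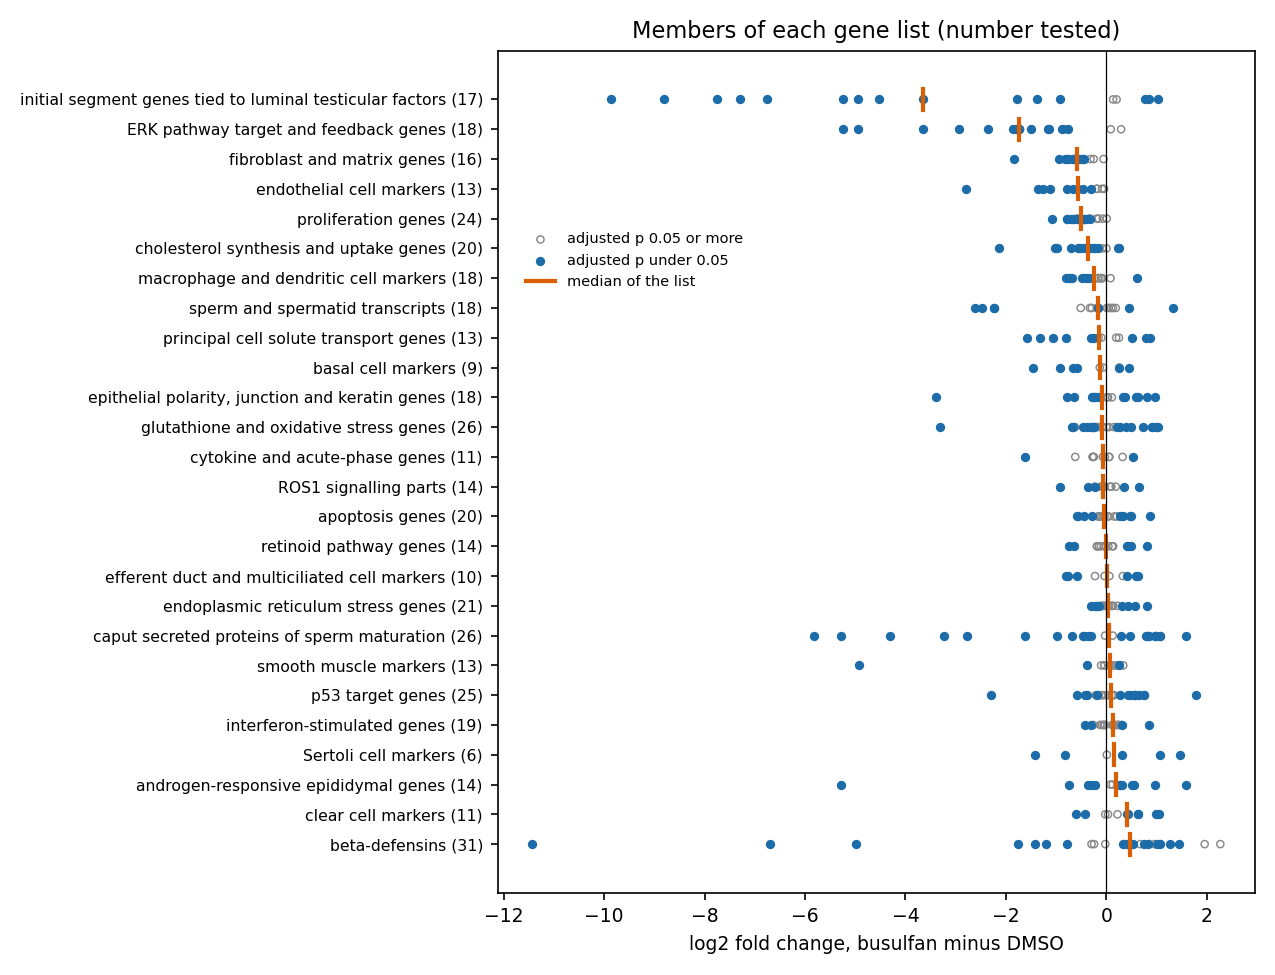
Log2 fold change (busulfan minus DMSO, on log2(FPKM + 1)) of each tested member of the 26 gene lists with at least 5 tested members, ordered by the list median (orange bar). Filled points passed an adjusted p of 0.05 and open points did not; the initial segment list has the lowest median (-3.64) and the β-defensins the highest (0.47), with members at -11.44 and -6.69.

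Of the 26 gene lists tested, 6 passed the threshold with the preset correlation, each toward lower values with busulfan, and 0 passed with an estimated correlation. Fry, which tests whether the members of a list move on balance in a single direction and does not compare a list with other genes, passed 16 lists.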

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

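The count of changed genes (5501) stayed within 1.5 times under a pseudocount of 0.1 (5479), no filter (5521 of 18750 tested), a mean of at least 5 FPKM (4405 of 9166), quantile normalization (5530), median scaling (5531), no trend (5357) and array weights (6317). A minimum log2 change of 1 left 575 genes, 140 higher and 435 lower, by its construction. Quantile normalization gave 3228 higher and 2302 lower (41.6% lower, against 51.5%), with a median log2 change of 0.037 over all tested genes. Without each library in turn, 4451 to 5054 genes changed (2127 to 2404 higher, 2324 to 2690 lower) and 6 to 7 lists passed. The labels do not say whether the replicate numbers pair the samples. Deviations of same-numbered libraries from their group means correlated at -0.18, -0.025 and -0.175, and those of different numbers at -0.046 to 0.229. Deviations cancel within a group of 3, so these correlations constrain each other and cannot show whether a pairing exists. With a replicate block 4627 genes changed, 2204 higher and 2423 lower, of which 4545 were shared with the fit without it in the same direction. Gpx5 (adjusted p = 0.224), Xbp1 (0.0555) and Hba-a1 (0.061) lost their calls under the block, and no other named gene or list call changed. The 6 list calls ended with an estimated correlation, which left 0 lists. The adjusted p of camera was then 0.7932 for the initial segment, ERK, endothelial, proliferation and cholesterol lists and 0.8623 for the fibroblast list. That setting allows for members that vary together, but what ended the calls was not tested. The p53 list, with an estimated correlation of 0.01, also moved, from 0.389 to 0.862. Fry, which does not compare a list with other genes, passed 16 lists, and the cause of its higher count was not tested. The proliferation list did not pass among genes with a mean of at least 5 FPKM (adjusted p = 0.4379), a filter that left 5 of its 24 members (2 lower, median log2 change -0.34, against -0.50 for the whole list); over its 12 alternatives the adjusted p ran from 1.06e-05 to 0.793. Leaving out libraries kept the adjusted p of the 6 lists at 6.516e-07 to 2.139e-05 (initial segment), 4.824e-11 to 3.404e-09 (ERK), 3.401e-05 to 0.001167 (fibroblast), 7.542e-05 to 0.0009931 (endothelial), 2.174e-05 to 0.0004317 (proliferation) and 4.419e-05 to 0.0002115 (cholesterol). Directions that reversed belonged to lists that did not pass by camera with the preset correlation, and the cause was not tested. They were the androgen-responsive list (0.9122) and smooth muscle list (0.8748) at a mean of at least 5 FPKM, the efferent duct, apoptosis and epithelial polarity lists after quantile normalization (0.97 each), and the androgen-responsive (0.005426), β-defensin (0.0136) and smooth muscle (0.09653) lists by fry, which called the androgen-responsive and β-defensin lists in the reversed direction. The smooth muscle list also reversed without DMSO replicate 2, busulfan replicate 1 or busulfan replicate 2 (0.3598 to 0.9461 over the 6 libraries left out), and the efferent duct list without DMSO replicate 3 or busulfan replicate 2 (0.8143 to 0.9856). The macrophage list passed without busulfan replicate 1 (0.00284). Among the named genes no direction changed. Pi16 lost its call without DMSO replicate 1 (adjusted p = 0.0584), Synm without DMSO replicate 2 (0.0539), Plk1 without DMSO replicate 2 or busulfan replicate 2 (0.0502 to 0.0638) and Rsad2 without DMSO replicate 3 or busulfan replicate 2 (0.0603 to 0.0614); the other losses stand beside the genes. The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 5501 changed genes and the highest other split 1, so 1 of the 10 splits gave as many. For gene lists the real split gave 6 and the highest other split 9, and 5 of the 10 splits gave at least 6. How depth limits calls was not tested by expression level.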

Other observations

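Genes outside the fixed lists were also far lower with busulfan, and the genes, families and groups described in this part were chosen after their values were seen. The tests of T and NK cells, macrophages, initial segment tissue and nuclear RNA were also chosen after the results were seen, whereas the length test and the neighbour test were set before. Among genes known from blood cells, the natural killer receptor gene Klrb1c fell from 147 ± 24.7 to 4.08 ± 0.129 FPKM, and the signalling and trafficking genes Zap70, Inpp5d and Acap1 and the class II accessory gene H2-DMb2 fell 99.0-fold, 17-fold, 97.5-fold and 24.9-fold. H2-DMb2 has a similar copy, H2-DMb1, which makes its value uncertain. The sialyltransferase genes St3gal2 and St6galnac2 fell from 146 ± 20.0 to 4.59 ± 0.367 FPKM and from 107 ± 4.0 to 7.45 ± 0.862 FPKM. Enpp2, which encodes the lysophospholipase autotaxin, fell from 189 ± 7.92 to 7.14 ± 0.870 FPKM, and the mitochondrial ribosomal protein gene Mrpl37 fell from 421 ± 17.5 to 22.8 ± 0.872 FPKM. The neurotensin receptor gene Ntsr1 was at 26.9, 31.7 and 26.3 FPKM in the DMSO libraries and listed at 0 in the 3 busulfan libraries. Vegfa, a ligand of the VEGF receptors, fell from 35.2 ± 2.33 to 21.1 ± 0.378 FPKM, and the growth factor gene Bmp7 and the receptor gene Met fell 5.58-fold and 3.79-fold. The DNA repair gene Mgmt, which removes alkyl groups from guanine, rose from 4.37 ± 1.59 to 12.3 ± 2.30 FPKM.

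A scan of 143 symbol families of at least 10 tested genes by camera found 6 past the threshold. The Dusp phosphatases (11 of 18 lower, median log2 change -0.39, adjusted p = 0.000707), the Col collagens (13 of 30 lower, -0.21, 0.0371) and genes whose symbols have St directly before a number, among them the sialyltransferases (9 of 16 lower, -0.32, 0.0453), were lower. The Zfp zinc finger genes (82 of 300 higher, median 0.13, camera adjusted p = 0.00206) were higher. So were genes whose symbols have Rpl (20 of 49 higher, 0.17, 0.00557) or Rps (20 of 44 higher, 0.20, 0.0122) directly before a number. These 2 families include ribosomal protein genes but were not restricted to them. The directions were the same after quantile normalization, and with an estimated correlation the adjusted p was at least 0.9 for each.

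The first pattern weighed is the fall of these 5 genes known from blood cells (Klrb1c, Zap70, Inpp5d, Acap1 and H2-DMb2), which were put together because they fell, by -5.20 to -3.78 on the log2 scale from DMSO means of 23.4 to 147 FPKM. Fewer T and NK cells are argued against, because the highest T and NK marker mean in the DMSO libraries was 0.975 FPKM, far below these genes. Fewer macrophages and dendritic cells are argued against by the median of their 18 tested markers, -0.25 (bootstrap 95% interval over genes -0.44 to -0.10). The bootstrap resampled genes, not samples, and the estimated correlation of these markers was 0.56. The interval therefore does not give the spread between samples. The class II genes fell most among the 18, but the largest fall, H2-Ab1 at -0.79, was far less than -3.78. A hypothesis that stays open is that the epithelium itself expresses these genes in the initial segment, and no test here separates cell types.

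The second pattern is the fall of the initial segment genes. Less initial segment tissue in the busulfan samples may contribute and cannot be told apart from lower expression per cell, because no library of a single segment was used. Of the 17 genes, 5 did not fall, and Ros1 kept 52.0% of its level while Lcn8 kept 0.216%. Which of them are restricted to the initial segment is not known from these libraries, so this spread does not decide. The busulfan treatment remains an open biological explanation. An action of the drug on the epididymis itself and an action through the loss of germ cells or testicular factors cannot be told apart here. Both would come with the same injection.

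The third pattern is that 19 of 23 tested transcripts with introns often detained in the nucleus rose and 0 fell (median log2 change 0.53), where 2668 of all 12848 tested genes rose. The set was put together after values were seen, so its count describes these libraries and is no test of the pattern. Among them Leng8 rose 2.58-fold, Rsrp1 2.02-fold, Pnisr 1.90-fold and Clk1 1.72-fold. Degraded RNA in the busulfan libraries is argued against only where it would lower long transcripts most. The fold change did not fall with the length of the longest annotated transcript (Spearman's rho = 0.036 across 12368 genes, which are not independent replicates). RNA quality and read coverage were not examined, so other or milder degradation is not decided. More nuclear RNA in the busulfan libraries stays open. Without Neat1 and Malat1, whose rise was known, 6 nuclear long noncoding RNAs had a median of 0.28. Its bootstrap 95% interval, over genes and not samples, was 0 to 1.09, which decides neither way. A change in the cells was not tested.

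A hypothesis was that chromosomal neighbours of strongly fallen genes fall too, beyond gene families. Of 162 genes lower by at least 2 on the log2 scale, 36 (22.2%) had a nearest tested neighbour with another symbol stem that was lower by at least 1. Random draws of genes gave a median of 5 and at most 16 (permutation p = 1e-04, the smallest that 10000 draws can give). The 36 hold 31 distinct pairs, since some genes are each other's neighbour; in this count, made after the result was seen, random draws gave a median of 5 and at most 18 distinct pairs (permutation p = 1e-04, again the smallest). Several also share a neighbour, such as Cst8, Cst11 and Cst12. Leaving out predicted, Rik, Prm, Tnp and Adam genes, a choice made after the result was seen, left 19 of 130, where random draws gave a median of 3 and at most 13. A pair of this kind is Mrpl37 (log2 change -4.15; chromosome 4, 107055874 to 107066868) and Cyb5rl (-1.72), which lie 120 bases apart. Of the 36, 15 lay within 10000 bases of the neighbour and 21 lay farther away, up to 2901560 bases. Reads that run on into a neighbour could bear mainly on the close pairs, and neither they nor shared regulation were tested.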
